A study of Mus musculus with 12 samples.

How the data were processed

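The series held 12 single-channel Affymetrix arrays of CD4+ T cells transduced with Foxp3 and Pparg1, with 3 arrays for each of 4 treatments: DMSO vehicle, GW1929, pioglitazone and rosiglitazone. Per the labels' protocols, RNA was extracted with TriZol and labelled with biotin by a whole-transcript terminal labelling kit. Per the series' design text, cells were sorted from pooled organs of several mice and each treatment was run in triplicate. The deposited values were linear-scale intensity per probe set, made by the authors with RMA, and they were converted to log2 for every test. The series' design text names GenePattern for this step, and the submitters' processing notes name RMA and Affymetrix Power Tools. Versions and the genome build of the annotation were not given in the sources used here. The table was taken as the authors had scaled it, with one column per array, and it held 0 columns of other series.

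The table held 25194 probe sets with intensities from 5.51 to 17563. The annotation tied 21181 probe sets to exactly 1 gene symbol, 1379 to several and 2634 to none. By Entrez number 21097 were matched to RefSeq, and 0 symbols changed. A gene with several probe sets (909 genes) was read from the one with the highest mean, which left 19537 genes. Of these, 7524 had a mean intensity of at least 120. No filter on intensity was applied before the tests. Probe sets without a single symbol were left out of the comparisons and tested apart. No 2 arrays had identical values. On principal components, the first held 38.9% and the second 13.6% of the variance.

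Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 12 arrays with 4 group means and no block, with 8 residual and 8.01 prior degrees of freedom. Contrasts were the mean of the 3 agonist groups against vehicle, each agonist against vehicle and each pair of agonists, and a moderated F-test asked for any difference among the agonists. Benjamini-Hochberg adjustment ran over all genes of a comparison, with a threshold of 0.05, and intervals are at 95%. Fold changes were compared across compounds by correlation and covariance, beside 100 simulated draws of unchanged groups (seed 11). Each draw shuffled the within-group deviations of all 12 arrays, flipped signs at random and let 3 of them stand as shared controls.

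The 34 gene lists (871 entries, 758 measured) were written from general knowledge, and 33 with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists. The list of mitochondrially encoded genes had 0 measured members. Camera was repeated with an estimated correlation, and fry served as a self-contained test. List members were counted over all genes and also adjusted over the list alone.

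The groups, tests, gene lists, alternatives and rule for named genes were fixed before the data were examined. Named were 15 genes in every case, of which Il1rl1 had no probe set of its own in the table. Added were the 12 largest rises and 12 largest falls against vehicle among called genes whose treated arrays all lay beyond all vehicle arrays, and the 5 largest in each direction between compounds. Also named were the 5 smallest p of the F-test, up to 4 members per list with the smallest p in the mean comparison, and, where a comparison called 0 genes, the 5 smallest p in each direction. Predicted genes, olfactory receptors and small RNAs with Mir or Snor names were skipped in the rankings and counted. Further list members, sorting markers and genes such as Prdx1, Rps20, Abca1 and E2f1 were chosen after their values were seen.

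Alternatives tried were quantile normalization, median centring, a minimum mean intensity of 120, a pseudocount of 16, an intensity trend with a robust prior, array weights (statmod 1.5.0), every probe set on its own, a fold change of at least 1.5, a replicate block, only the 6 arrays compared and leaving out each array. Cyclic loess normalization and a covariate for the largest direction of spread within groups (the gradient) were added after the data were seen. The pipeline was tested on simulated data: of 50 genes moved by 0.5 on the log2 scale 92% were recovered, and of those moved by 0.8 or more 100%, with 5.8% false calls. An unchanged comparison called 0 genes and 0 lists, and a list shifted by 0.2 was called. The simulated noise was drawn independently for each gene and array. These values therefore do not show how the tests behave where genes or arrays vary together. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.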

Results

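The data set held 12 Affymetrix arrays of mouse T cells. CD4+ CD3+ T cells without Foxp3 were sorted from pooled spleens and lymph nodes of male C57BL/6 mice and transduced with Foxp3, the lineage transcription factor of regulatory T cells (Treg cells), together with Pparg1, a form of the nuclear receptor PPARγ. The transduced cells were then treated with the solvent DMSO (vehicle) or with 1 of 3 PPARγ agonists. Pioglitazone and rosiglitazone are thiazolidinediones, and GW1929 is a tyrosine-derived agonist without the thiazolidinedione ring. Each of the 4 groups had 3 arrays, and the labels gave no dose and no time of treatment. Every array carried 25194 probe sets, array medians lay between 69.1 and 76.0 intensity units, and correlations between arrays across probe sets ran from 0.9865 to 0.9972. No group without transduction was analysed here, so the comparisons ask what the ligands changed in cells that already carried both genes. The number of arrays limits the precision, with a median standard error of 0.093 (log2) for a difference between 2 groups. Cells of several mice were pooled, and the labels do not say that the arrays of a group came from separate pools, so p-values measure the spread between these arrays, which may be technical.

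Both transduced genes were bright in all groups. Foxp3 had a geometric mean intensity of 2684 with vehicle, 3180 with GW1929, 3000 with pioglitazone and 2586 with rosiglitazone (n = 3 each), and its difference between the mean of the agonists and vehicle was 0.12 ± 0.066 (log2 ± SE; adjusted p = 0.97). Pparg stood at 680.3, 909.0, 739.7 and 736.2 in the same order, a difference of 0.22 ± 0.096 (adjusted p = 0.97). Its largest difference, GW1929 against vehicle, was 0.42 ± 0.12 (adjusted p = 0.105). Transcripts of T cells were abundant, with a mean intensity of 3505 for Cd3g, 3501 for Cd3e and 3260 for Cd4. Markers of the cell types removed by sorting were dim: 18.0 for Cd79a of B cells, 23.6 for Lyz2 of macrophages, 17.5 for S100a8 of neutrophils, 51.4 for Cd8a and 13.4 for Klrb1c, which encodes NK1.1. Brighter markers of other cells were Cd8b1 at 210.3, the B cell gene Cd72 at 140.9, the protease gene Ctss at 264.4 and Pecam1, an endothelial marker that leukocytes also carry, at 992.9.

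When the mean of the 3 agonist groups was compared with vehicle, 2 of 19537 genes rose and 0 fell. Plin2, which encodes the lipid droplet coat protein perilipin 2 and is a classical PPAR target, rose 1.87-fold (log2 0.90 ± 0.098, 95% interval 0.70 to 1.11, adjusted p = 0.00163). Its intensity was 102.4, 90.9 and 85.1 on the vehicle arrays and between 145.8 and 212.3 on the 9 agonist arrays. Fam183b, a little studied gene linked to ciliated cells, rose 2.01-fold (log2 1.01 ± 0.14, interval 0.71 to 1.31, adjusted p = 0.0209), from 72.6 with vehicle to 147.2, 145.3 and 145.9 with GW1929, pioglitazone and rosiglitazone. Plin2 and Fam183b were higher on 9 of 9 agonist arrays than on any vehicle array. At an unadjusted p under 0.05, limma counted 954 genes. The Plin2 call held under 21 of 21 alternatives, with a highest adjusted p of 0.0479 without vehicle replicate 3. The Fam183b call held under 13 of 21 and ended, among others, after cyclic loess normalization (adjusted p = 0.0523) and without vehicle replicate 1 or 3.

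**Figure D1:**
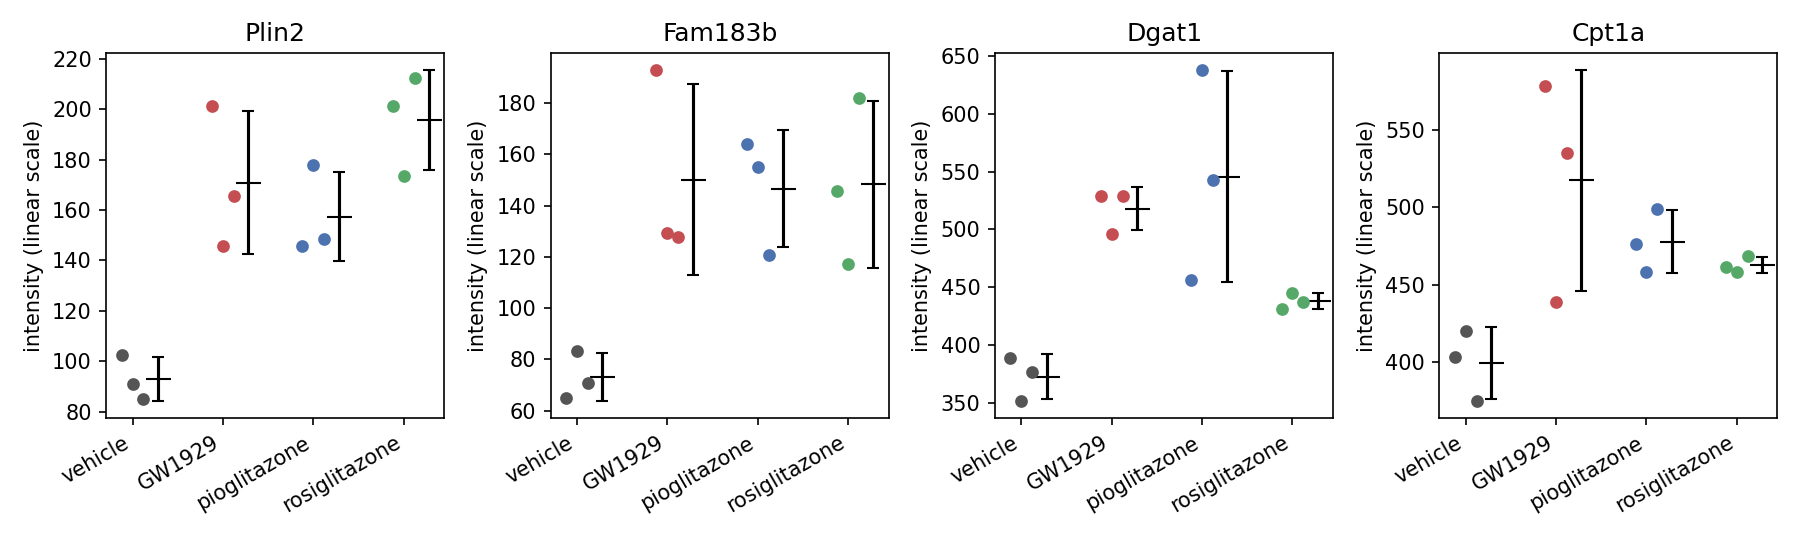
Linear intensity of Plin2, Fam183b, Dgat1 and Cpt1a on each array (points) by treatment, with the mean and SD of each group (black bars, n = 3). Plin2 lay at 85.1 to 102.4 with vehicle and at 145.8 to 212.3 with the agonists, and Dgat1 at 351.4 to 389.3 with vehicle and 431.4 to 638.1 with the agonists.

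Other genes of lipid handling had smaller differences that did not pass over all genes. Dgat1, the enzyme of the last step of triglyceride synthesis, differed by 0.42 ± 0.081 (adjusted p = 0.229), and Cpt1a, which carries fatty acids into mitochondrial oxidation, by 0.28 ± 0.076 (adjusted p = 0.793). Among 25 measured genes of lipid droplets and triglyceride storage 1 rose, Plin2, and 2 rose when adjusted over the list alone. Of 27 PPARG targets of adipocytes 1 rose, also 1 when adjusted over the list alone, and 20 lay above 0. Several well-known adipocyte targets were near background, such as the fatty acid carriers Cd36 at an intensity of 13.5 (0.051 ± 0.072) and Fabp4 at 13.4 (0.004 ± 0.064). Angptl4 differed by 0.070 ± 0.096 and Pdk4 by 0.078 ± 0.086 (adjusted p = 0.974 and adjusted p = 0.97). Fatty acid oxidation had 0 of 30 members past the threshold, with Etfb at 0.26 ± 0.087 (adjusted p = 0.898) and Slc22a5 at 0.17 ± 0.068 (adjusted p = 0.961).

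Genes that mark Treg cells and those of visceral fat had 0 members past the threshold over all genes. In the fixed list of visceral fat Treg markers 21 of 28 members lay above 0 and 2 rose when adjusted over the list alone. Dgat1 led it, followed by Odc1, which encodes the first enzyme of polyamine synthesis (0.26 ± 0.068, adjusted p = 0.699). In the raised part of the Treg signature 26 of 36 members lay above 0 and 0 rose when adjusted over the list alone. Its leading members were Lrrc32, the docking receptor of latent TGF-β (0.38 ± 0.13, adjusted p = 0.896), and Penk, the proenkephalin gene (0.62 ± 0.22, adjusted p = 0.961). Il2ra differed by 0.071 ± 0.065, Ctla4 by -0.003 ± 0.078, Gata3 by 0.027 ± 0.072, Il10 by 0.036 ± 0.077, Ccr2 by 0.065 ± 0.12 and Klrg1 by 0.076 ± 0.073, with adjusted p values of 0.97 or higher.

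In camera, a test of a list against all other genes, 4 of 33 lists passed for the mean of the agonists. Visceral fat Treg markers (median 0.051, adjusted p = 0.00713), the raised Treg signature (0.039, adjusted p = 0.0111) and glycolysis and hypoxia genes (0.064, adjusted p = 0.0111) were shifted up. Proliferation genes were shifted down (median -0.079, adjusted p = 0.00047). The compounds differed, as the log2 deviations of list means from the mean of all arrays show. Proliferation stood at 0.064 with vehicle, -0.203 with GW1929, 0.11 with pioglitazone and 0.028 with rosiglitazone. Its fall was thus mainly that of GW1929, and pioglitazone lay above vehicle. Glycolysis and hypoxia stood at -0.048, -0.047, 0.063 and 0.032 in the same order, so GW1929 lay near vehicle. In both Treg lists every compound lay above vehicle. All 4 called lists had adjusted p = 0.443 with an estimated correlation and were lost by fry. Both Treg lists also lost the call without vehicle replicate 1 or GW1929 replicate 1, proliferation at a mean intensity of at least 120 or without vehicle replicate 1, and glycolysis without vehicle replicate 2. PPARG adipocyte targets (0.041, adjusted p = 0.0577), LXR targets (0.074, adjusted p = 0.0577), Th1 and cytotoxic genes (0.017, adjusted p = 0.0634), the interferon gamma response (0.065, adjusted p = 0.0634), heat shock (-0.073, adjusted p = 0.0634) and Th2 genes (0.048, adjusted p = 0.0728) stayed above the threshold.

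The remaining lists had adjusted p values of 0.14 or more in this comparison. Their medians were 0.003 for lipid droplets, 0.012 for fatty acid oxidation, 0.011 for cholesterol synthesis, 0.044 for fatty acid synthesis, -0.016 for the lowered Treg signature and 0.002 for Th17 genes. They were 0.020 for chemokine receptors and homing, 0.014 for NF-kB targets, -0.003 for the type I interferon response, -0.008 for oxidative phosphorylation, -0.013 for the ER stress and amino acid response, 0.017 for NRF2 targets, -0.019 for p53 targets, 0.040 for immediate early genes, 0.027 for ribosomal proteins and 0.050 for histone genes. Markers of other cells had medians of 0.014 for B cells, -0.033 for macrophages and dendritic cells, 0.030 for neutrophils, 0 for NK and CD8 T cells, -0.010 for erythroid cells and platelets and -0.026 for stromal and endothelial cells. T cell identity genes stood at 0.023. Median and mean differed in sign for cholesterol synthesis (0.011 and -0.009), neutrophil markers (0.030 and -0.007) and erythroid and platelet markers (-0.010 and 0.039), and the camera direction was up, down and up for these.

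GW1929 against vehicle gave the largest set of changes against the solvent, with 75 genes higher and 40 lower. Of 39 measured proliferation genes 7 fell, 0 rose and 32 did not pass, while 20 fell when adjusted over the list alone. Top2a, the topoisomerase that untangles replicated chromosomes, fell by 0.78 on the log2 scale (SE 0.16, n = 3 per group, adjusted p = 0.0353), and the mitotic checkpoint kinase gene Bub1 by 0.75 (SE 0.13, adjusted p = 0.0223). The spindle genes Kif11 (-0.57 ± 0.11), Tpx2 (-0.53 ± 0.095) and Prc1 (-0.47 ± 0.10), the checkpoint gene Bub1b (-0.47 ± 0.094) and the ribonucleotide reductase gene Rrm2 (-0.44 ± 0.090) fell as well. Plin2 rose 1.83-fold (0.87 ± 0.12, adjusted p = 0.0105), Fam183b 2.03-fold (1.02 ± 0.17, adjusted p = 0.0196) and Dgat1 1.39-fold (0.48 ± 0.099, adjusted p = 0.0446).

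Mki67, the gene of the proliferation antigen Ki-67, stood at -0.42 ± 0.10 (adjusted p = 0.0686), Cdk1 at -0.42 ± 0.12 (adjusted p = 0.0943) and Ccna2 at -0.55 ± 0.16 (adjusted p = 0.12). Members with values near 0 included Mcm2 (0.028 ± 0.091), Tk1 (0.019 ± 0.097) and E2f1 (0.095 ± 0.090). The list median was -0.31 (camera adjusted p = 8.28e-13), with adjusted p = 0.262 with an estimated correlation. The list's call was also lost by fry, which called 0 lists in this comparison (smallest fry adjusted p = 0.0791). Depdc1a (-0.69 ± 0.14) and Hmmr (-0.58 ± 0.11), both of the mitotic spindle but outside the list, were among the 12 largest falls, as were Gskip (-0.71 ± 0.14), Fam136a (-0.68 ± 0.12), Pcmt1 (-0.66 ± 0.14), the proteasome subunit gene Psma6 (-0.61 ± 0.12), Cbr4 (-0.58 ± 0.12), the ubiquitin-conjugating enzyme gene Ube2n (-0.58 ± 0.10) and Zdhhc2 (-0.58 ± 0.11).

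Srsy, a Y-linked multicopy gene of spermatids, had the largest rise (1.55 ± 0.26, adjusted p = 0.0183). It was followed, after Fam183b and Plin2, by the transporter genes Slc10a4 (0.77 ± 0.13) and Slc43a1 (0.64 ± 0.11), AY036118 (0.60 ± 0.11), Phxr4 (0.59 ± 0.12), the vomeronasal receptor genes Vmn1r193 (0.59 ± 0.12) and Vmn1r208 (0.55 ± 0.084), Chil3 (0.57 ± 0.10), Insyn2b (0.56 ± 0.093) and Igha (0.56 ± 0.11). Chil3 is a macrophage product and Igha the constant region of IgA, and both were dim, at 21 and 49.5. Of the 75 genes that rose, 61 had a mean intensity under 120, and 33 of the 115 calls were olfactory, vomeronasal or taste receptors, while 25 of the 40 that fell were at 120 or above. With all genes ordered by intensity in 10 equal bins, the median difference was 0.093 in the dimmest bin and -0.067 in bin 9.

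The oxidative phosphorylation list had a median of -0.063 (camera adjusted p = 0.00804; adjusted p = 0.707 with an estimated correlation). In it 1 of 44 genes fell, the ATP synthase gene Atp5pb (-0.46 ± 0.087, adjusted p = 0.0296), with 9 lower and 1 higher when adjusted over the list alone. Heat shock genes had 0 of 12 past the threshold and a median of -0.16 (camera adjusted p = 0.00994; adjusted p = 0.262 with an estimated correlation). Both calls were also lost after quantile normalization, after cyclic loess, at a mean intensity of at least 120 and by fry, and that of oxidative phosphorylation without vehicle replicate 1 or GW1929 replicate 1, with a median as small as -0.006. Single members passed in other lists: the linker histone gene H1f2 rose (0.34 ± 0.069, adjusted p = 0.0364) and the interferon-induced gene Rtp4 fell (-0.46 ± 0.10, adjusted p = 0.049).

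By limma, 3713 genes had an unadjusted p under 0.05. The count was 180 without vehicle replicate 1, 46 without vehicle replicate 2, 5 without vehicle replicate 3, and 64, 29 and 27 without GW1929 replicates 1, 2 and 3. It was 33 after cyclic loess and 36 after quantile normalization, where 81.8% and 75% of the calls were higher against 65.2% in the table as deposited, and 31 after median centring (80.6% higher). With the gradient as a covariate 82 genes were called, 70 higher and 12 lower, 63 of them among the original 115. The replicate block gave 13 higher and 1 lower. Lower genes were the larger part without vehicle replicate 1 (34.4% higher), with array weights (40% of 1199 higher) and with only the 6 arrays compared (45.2% of 177 higher). The Top2a call was kept under 4 of 16 alternatives, that of Bub1 under 8 of 15, Kif11 under 4 of 16, that of Plin2 under 15 of 16, and Igha under 4 of 15. Among the other largest rises, Vmn1r208 (14 of 15) and Insyn2b (13 of 15) were kept most often and Chil3 (5 of 15) least. Among the other largest falls, Ube2n (9 of 16) was kept most often and Gskip (3 of 16) least.

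**Figure D2:**
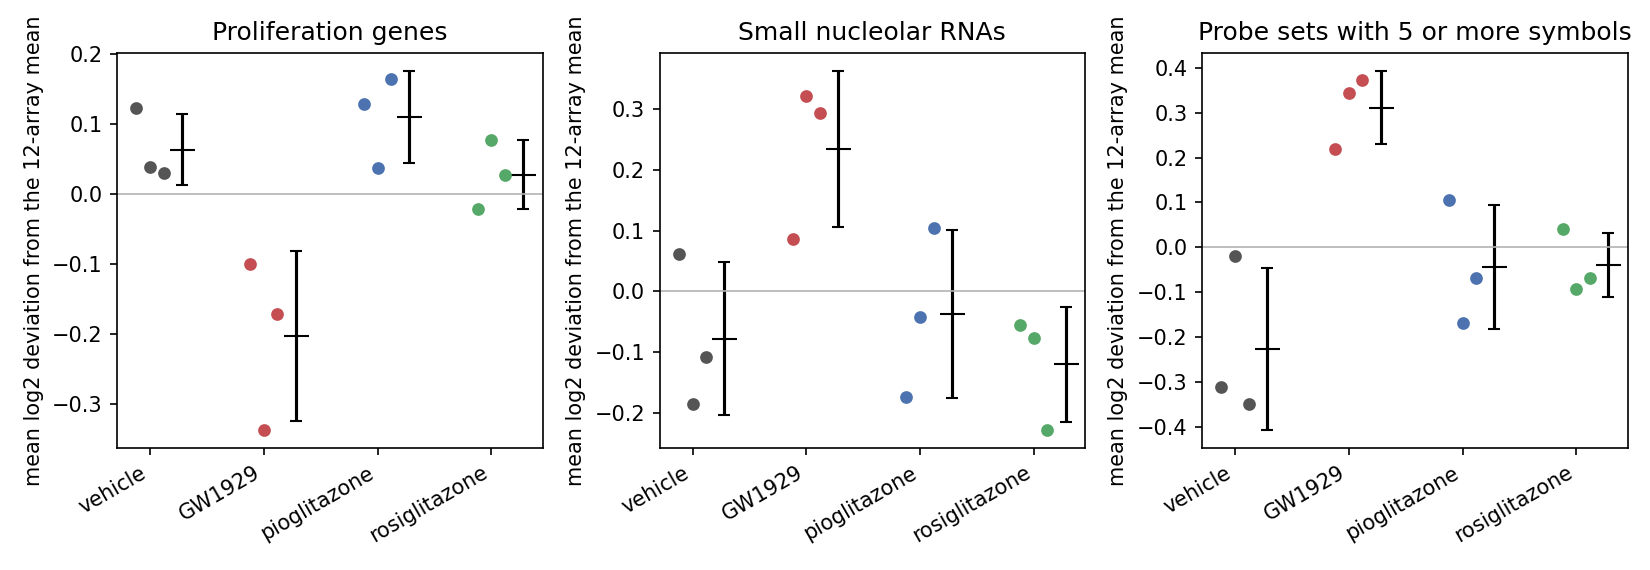
Mean log2 deviation from the 12-array mean, per array (points) and by treatment, of the 39 proliferation genes, 44 small nucleolar RNAs and 356 probe sets annotated to 5 or more symbols, with the mean and SD of each group (black bars, n = 3). GW1929 arrays lay at -0.10, -0.34 and -0.17 for proliferation genes, and the other 9 arrays between -0.021 and 0.17.

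**Figure D3:**
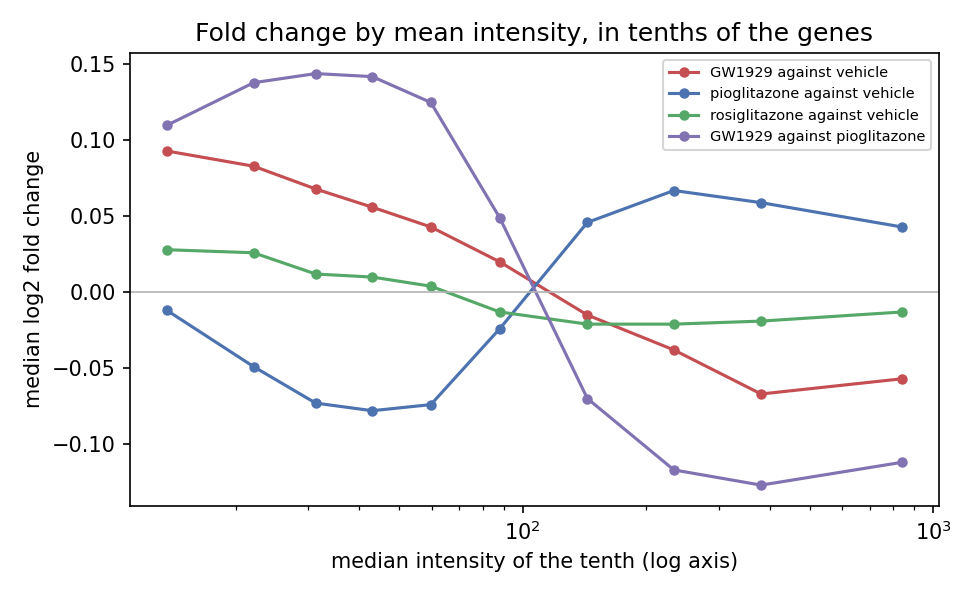
Median log2 fold change of 10 equal bins of genes ordered by mean intensity (log axis), with 1 line per comparison. GW1929 against pioglitazone ran from 0.14 in a dim bin (bin 3) to -0.13 in bin 9, and pioglitazone against vehicle from -0.078 to 0.067.

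Pioglitazone against vehicle called 0 genes by limma, with a smallest adjusted p of 0.19 for Plin2 and 1642 genes at an unadjusted p under 0.05. On the first principal component the pioglitazone arrays lay at 22.9, -2.5 and 7.4, and the vehicle arrays at -6, 8 and 9.9. Pioglitazone replicate 2 had a mean correlation of 0.9941 with its own group and 0.9951 with the other groups. Plin2 stood at 0.76 ± 0.12 (n = 3 per group) and Fam183b at 1.00 ± 0.17 (adjusted p = 0.251). Next came Dgat1 (0.54 ± 0.099, adjusted p = 0.374), Odc1 (0.43 ± 0.083, adjusted p = 0.382) and the interleukin 12 receptor gene Il12rb2 (0.44 ± 0.091, adjusted p = 0.424). On the lower side were Sbpl (-0.64 ± 0.12), Usp17lc (-0.38 ± 0.076), Hoxc10 (-0.48 ± 0.10), Usp43 (-0.39 ± 0.089) and Igfn1 (-0.37 ± 0.084). Plin2 passed after median centring (adjusted p = 0.0414), with array weights (adjusted p = 0.0386) and with the gradient as a covariate (adjusted p = 0.0289). Dgat1 passed with array weights (adjusted p = 0.0386), with the gradient as a covariate (adjusted p = 0.0289) and without pioglitazone replicate 1 (adjusted p = 0.031).

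Camera called 13 lists for pioglitazone, 11 shifted up and 2 down, with 0 members called over all genes. The interferon gamma response had 19 of 20 members above 0 (median 0.15, adjusted p = 1.69e-05; adjusted p = 0.0904 with an estimated correlation), led by the GTPase genes Iigp1 (0.44 ± 0.12) and Gbp3 (0.28 ± 0.097). The raised Treg signature had 31 of 36 above 0 (median 0.11, adjusted p = 1.14e-06; adjusted p = 0.0911 with an estimated correlation), with the ectonucleotidase gene Entpd1 at 0.30 ± 0.081 and Socs2 at 0.32 ± 0.10. Glycolysis and hypoxia genes (median 0.12, adjusted p = 4.75e-05), fatty acid oxidation (0.078, adjusted p = 0.00209), Th1 and cytotoxic genes (0.083, adjusted p = 0.00438) and the type I interferon response (0.044, adjusted p = 0.0197) each had adjusted p = 0.0911 with an estimated correlation. NF-kB targets (0.13, adjusted p = 0.00343), visceral fat Treg markers (0.061, adjusted p = 0.0123) and p53 targets (0.097, adjusted p = 0.044) had adjusted p = 0.227 with an estimated correlation.

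LXR targets (0.058, adjusted p = 0.0141) had adjusted p = 0.253 with an estimated correlation, and proliferation genes (0.062, adjusted p = 0.049) adjusted p = 0.565. Markers of stromal and endothelial cells were shifted down (median -0.13, adjusted p = 0.00154; adjusted p = 0.227 with an estimated correlation), as were neutrophil markers (-0.074, adjusted p = 0.044; adjusted p = 0.421 with an estimated correlation). Their leading members were dim, with Sparc at an intensity of 52.9 (-0.34 ± 0.083) and Csf3r at 30 (-0.34 ± 0.093). Over all genes the median difference ran from -0.078 in intensity bin 4 to 0.067 in bin 8, so dim lists and bright lists were set against a moving background. By fry 0 of the 13 lists passed. After quantile normalization the calls of fatty acid oxidation, NF-kB targets, type I interferon, proliferation, p53, neutrophil and stromal genes were lost, and after cyclic loess those of fatty acid oxidation, proliferation, p53 and neutrophil genes. At a mean intensity of at least 120 those of fatty acid oxidation, LXR targets, Th1 genes, type I interferon and p53 targets were lost. Leaving out 1 array ended the calls of LXR targets (vehicle 2, pioglitazone 2 or 3), Th1 genes (vehicle 2), type I interferon (vehicle 3, pioglitazone 1), proliferation (vehicle 2 or 3, pioglitazone 1 or 3), p53 targets (vehicle 2, any pioglitazone array) and neutrophil markers (vehicle 2, pioglitazone 1 or 3).

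Rosiglitazone against vehicle called 1 gene. Plin2 rose 2.11-fold (1.08 ± 0.12, interval 0.82 to 1.33, n = 3 per group, adjusted p = 0.00237), and this call held under 16 of 16 alternatives. Fam183b stood at 1.01 ± 0.17 (adjusted p = 0.122). Dgat1 at 0.24 ± 0.099 and Cpt1a at 0.21 ± 0.093 had adjusted p = 1, and limma counted 751 genes at an unadjusted p under 0.05. Camera called 1 list, glycolysis and hypoxia, with 24 of 29 members above 0 (median 0.10, adjusted p = 0.00294; adjusted p = 0.625 with an estimated correlation) and 0 members called, led by the hexokinase gene Hk1 (0.17 ± 0.076). It was lost by fry and without vehicle replicate 2. PPARG adipocyte targets had a median of 0.035 (camera adjusted p = 0.276).

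Between the thiazolidinediones, rosiglitazone and pioglitazone, 0 genes differed by limma, with 2511 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0696. The difference of the Plin2 response was 0.32 ± 0.12 with a 95% interval of 0.061 to 0.57 (adjusted p = 0.317), that of Fam183b 0.005 ± 0.17 (-0.36 to 0.37, adjusted p = 0.992) and that of Dgat1 -0.30 ± 0.099 (-0.51 to -0.093, adjusted p = 0.283). The smallest p on the higher side belonged to Usp17lc (0.52 ± 0.076, adjusted p = 0.0696), Crym, which encodes a thyroid hormone binding protein (0.49 ± 0.093), Timm8a1 (0.49 ± 0.096), Krt87 (0.41 ± 0.081) and Fndc7 (0.40 ± 0.083). On the lower side they were Lrrc61 (-0.46 ± 0.079), the AP-1 gene Fosl2 (-0.43 ± 0.081), Pias3 (-0.46 ± 0.086), the aryl hydrocarbon receptor gene Ahr (-0.45 ± 0.085) and Tbc1d30 (-0.44 ± 0.086), with adjusted p of 0.179 each. With array weights limma called 247 genes between these compounds, and all of the genes just named were among them. Usp17lc and Lrrc61 were also called with the gradient as a covariate. Doses and times were not given, so it is not known whether the compounds were matched.

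Camera called 12 lists between these compounds, 10 lower and 2 higher with rosiglitazone, and 0 with an estimated correlation. Lower were the raised Treg signature (median -0.079, adjusted p = 0.00131), NF-kB targets (-0.11, adjusted p = 0.00174), the type I interferon response (-0.11, adjusted p = 0.00171), the interferon gamma response (-0.11, adjusted p = 0.00212), p53 targets (-0.090, adjusted p = 0.00254) and immediate early genes (-0.091, adjusted p = 0.00268). In that order they had adjusted p = 0.259, adjusted p = 0.203, adjusted p = 0.0887, adjusted p = 0.152, adjusted p = 0.152 and adjusted p = 0.368 with an estimated correlation. Also lower were proliferation genes (-0.080, adjusted p = 0.0111), T cell identity (-0.082, adjusted p = 0.0111), Th1 and cytotoxic genes (-0.074, adjusted p = 0.0371) and histone genes (-0.070, adjusted p = 0.0428), with adjusted p = 0.566, adjusted p = 0.368, adjusted p = 0.203 and adjusted p = 0.566 with an estimated correlation. Stromal and endothelial markers (0.17, adjusted p = 0.000812) and erythroid and platelet markers (0.16, adjusted p = 0.0102) were higher, both at adjusted p = 0.203 with an estimated correlation. Among the immediate early genes 7 were lower when adjusted over the list alone, with Egr1 at -0.49 ± 0.10 (adjusted p = 0.189) and Zfp36 at -0.40 ± 0.091 (adjusted p = 0.197). By fry 5 lists passed: both interferon lists, p53 targets and the 2 higher marker lists. The interferon gamma, proliferation, histone and T cell identity calls were lost after quantile normalization and cyclic loess. At a mean intensity of at least 120 those of the Treg signature, Th1, both interferon, p53 and T cell identity lists were lost. Leaving out 1 array ended the calls of Th1 genes (pioglitazone 3, rosiglitazone 3), proliferation (pioglitazone 3, rosiglitazone 1), immediate early genes (pioglitazone 2), histone genes (pioglitazone 2 or 3, rosiglitazone 3) and T cell identity (pioglitazone 2).

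With GW1929, 645 genes were higher and 487 lower than with pioglitazone, and 12 of 39 proliferation genes were lower (24 when adjusted over the list alone). Tpx2 was lower by -0.69 ± 0.095 (n = 3 per group, adjusted p = 0.00636), Bub1 by -0.82 ± 0.13 (adjusted p = 0.0106), Top2a by -0.80 ± 0.16 (adjusted p = 0.0233) and Mki67 by -0.48 ± 0.10 (adjusted p = 0.0269). The proliferation list had a median of -0.31 (camera adjusted p = 8.79e-13; adjusted p = 0.105 with an estimated correlation). Plin2 differed by 0.11 ± 0.12 (interval -0.14 to 0.37, adjusted p = 0.526), Fam183b by 0.018 ± 0.17 (-0.35 to 0.38) and Dgat1 by -0.063 ± 0.099 (-0.27 to 0.15).

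Between GW1929 and pioglitazone, 5 of 20 members of the interferon gamma list passed, all lower with GW1929, and 7 when adjusted over the list alone (median -0.12, camera adjusted p = 0.00461; adjusted p = 0.117 with an estimated correlation). Iigp1, a GTPase of pathogen vacuoles, had -0.83 ± 0.12 (adjusted p = 0.00636), its relative Irgm1 -0.50 ± 0.099, Gbp5 -0.43 ± 0.10 and the transcription factor gene Irf1 -0.37 ± 0.093. In the type I list 3 of 29 were lower, Rtp4 (-0.59 ± 0.10), the RNA helicase gene Dhx58 (-0.33 ± 0.081) and Parp14 (-0.28 ± 0.078), and 6 when adjusted over the list alone (median -0.094, camera adjusted p = 0.00461; adjusted p = 0.0723 with an estimated correlation). Both list calls were also lost after quantile normalization, after cyclic loess and at a mean intensity of at least 120.

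Single genes of the Treg signature and of metabolism also differed between these compounds. Of 36 raised Treg signature genes 5 were lower and 1 higher (7 lower and 1 higher when adjusted over the list alone), with Socs2 at -0.54 ± 0.10, Entpd1 at -0.44 ± 0.081, the costimulator gene Icos at -0.36 ± 0.10 and Rgs16 at 0.31 ± 0.086 (list median -0.095, camera adjusted p = 0.00461; adjusted p = 0.318 with an estimated correlation). Fatty acid oxidation had 3 of 30 lower (6 adjusted over the list alone), the enzyme genes Eci2 (-0.59 ± 0.12) and Acadl (-0.39 ± 0.11) and the carnitine carrier gene Slc25a20 (-0.32 ± 0.077), with a median of -0.13 (camera adjusted p = 0.000539; adjusted p = 0.0723 with an estimated correlation). Oxidative phosphorylation had 4 of 44 lower, among them Ndufb6 (-0.67 ± 0.14) and Uqcrc2 (-0.37 ± 0.091), with a median of -0.14 (camera adjusted p = 0.000522; adjusted p = 0.388 with an estimated correlation). Both metabolic list calls were also lost after quantile normalization, after cyclic loess and at a mean intensity of at least 120, that of oxidative phosphorylation by fry as well, and the Treg list call after quantile normalization, after cyclic loess and by fry. Odc1 was lower by -0.47 ± 0.083 (adjusted p = 0.015), and the cholesterol exporter gene Abca1 by -0.36 ± 0.083 (adjusted p = 0.0338).

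The other camera calls of this comparison were glycolysis and hypoxia (median -0.13, adjusted p = 0.00245), the ER stress and amino acid response (-0.091, adjusted p = 0.00678), p53 targets (-0.18, adjusted p = 0.00151) and heat shock (-0.18, adjusted p = 0.0133). They had adjusted p = 0.135, adjusted p = 0.0723, adjusted p = 0.0723 and adjusted p = 0.182 with an estimated correlation. Markers of other cells were shifted up, stromal and endothelial ones by a median of 0.18 (adjusted p = 0.003), neutrophil ones by 0.14 (adjusted p = 0.0163) and erythroid and platelet ones by 0.21 (adjusted p = 0.0215). With an estimated correlation these had adjusted p = 0.272, adjusted p = 0.388 and adjusted p = 0.201. Their called members were dim, such as Sparc (0.30 ± 0.083, intensity 52.9), Lcn2 (0.35 ± 0.099, intensity 32.2) and Gp9 (0.31 ± 0.078, intensity 75.9). All 7 calls of this paragraph were lost after quantile normalization and cyclic loess, and the 4 lower ones also at a mean intensity of at least 120. The neutrophil call was lost without GW1929 replicate 1 and the erythroid call without GW1929 replicate 2.

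Krtap5-3, a keratin-associated protein gene, was the largest rise (0.95 ± 0.12, adjusted p = 0.00636), followed by Acot3 (0.74 ± 0.11), a peroxisomal acyl-CoA thioesterase gene, Vmn2r9 (0.73 ± 0.19), the small nucleolar RNA gene Rnu3a (0.72 ± 0.18) and the minor spliceosome RNA gene Rnu12 (0.70 ± 0.14). Depdc1a (-0.98 ± 0.14), Zfp975 (-0.91 ± 0.20), Iigp1, Bub1 and Top2a had the largest falls. The calls of Krtap5-3, Acot3, Depdc1a, Iigp1 and Bub1 were kept under all alternatives tried, those of Vmn2r9 under 3 of 15, Rnu3a under 5 of 16, Rnu12 under 11 of 16, Zfp975 under 8 of 15 and Top2a under 10 of 16. Of the 645 higher genes 601 were dimmer than 120, and of the 487 lower ones 347 were at 120 or above. Limma counted 6158 genes at an unadjusted p under 0.05. The count fell to 86 after cyclic loess and 105 after quantile normalization, was 210 and 90 without GW1929 replicates 1 and 2 and 622 without the third, and was 88, 3028 and 47 without pioglitazone replicates 1, 2 and 3. The share of calls that were higher was 57.0% as deposited, 46.5% after cyclic loess and 16.8% after median centring, which shifts all genes of an array alike.

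Against rosiglitazone, GW1929 gave 63 higher and 77 lower genes. Of 44 oxidative phosphorylation genes 5 were lower: Ndufb6 of complex I by -0.97 ± 0.14 (n = 3 per group, adjusted p = 0.013), Ndufa6 by -0.81 ± 0.17 (adjusted p = 0.0418) and the ATP synthase genes Atp5a1, Atp5c1 and Atp5pb by -0.52 ± 0.086, -0.57 ± 0.10 and -0.50 ± 0.087. When adjusted over the list alone 13 were lower and 3 higher. Among proliferation genes 5 of 39 were lower, 15 when adjusted over the list alone, with Rrm2 at -0.62 ± 0.090 (adjusted p = 0.0123), Top2a at -0.77 ± 0.16 and Cdk1 at -0.54 ± 0.12. The immediate early gene Egr1 was higher (0.52 ± 0.10, adjusted p = 0.0306), as was H1f2 (0.38 ± 0.069). Socs2 (-0.55 ± 0.10), Odc1 (-0.44 ± 0.083), the peroxiredoxin gene Prdx1 (-0.67 ± 0.11), the ribosomal protein gene Rps20 (-0.59 ± 0.12) and Hk1 (-0.34 ± 0.076) were lower.

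The largest rises were the small RNA genes Vaultrc5 (0.79 ± 0.14) and Rnu12 (0.72 ± 0.14), Fbrs (0.60 ± 0.11), Scp2d1 (0.60 ± 0.10) and Acot3 (0.59 ± 0.11). Next to Ndufb6 and Ndufa6, the largest falls were the mRNA export gene Alyref (-0.96 ± 0.17), the mitochondrial peroxiredoxin gene Prdx3 (-0.83 ± 0.15) and S100a10 (-0.81 ± 0.13). Of these 10 calls, that of Ndufb6 was kept most often, under 13 of 16 alternatives, and those of Ndufa6 (6 of 16), Vaultrc5 (7 of 15) and Acot3 (7 of 15) least often. Camera called proliferation (median -0.24, adjusted p = 5.8e-11; adjusted p = 0.303 with an estimated correlation), oxidative phosphorylation (-0.074, adjusted p = 0.00167; adjusted p = 0.722 with an estimated correlation, and lost after quantile normalization, after cyclic loess and at a mean intensity of at least 120) and fatty acid oxidation (-0.11, adjusted p = 0.00896; adjusted p = 0.303 with an estimated correlation). It also called glycolysis and hypoxia (-0.057, adjusted p = 0.00896; adjusted p = 0.38 with an estimated correlation), heat shock (-0.10, adjusted p = 0.0386; adjusted p = 0.38 with an estimated correlation), immediate early genes (0.14, adjusted p = 0.00335; adjusted p = 0.639 with an estimated correlation) and histone genes (0.22, adjusted p = 0.00814; adjusted p = 0.639 with an estimated correlation). By fry 0 of these lists passed. The histone call was also lost with the gradient as a covariate, and its median was as small as 0.060 under an alternative. Fatty acid oxidation, glycolysis and heat shock were also lost after quantile normalization, after cyclic loess and at a mean intensity of at least 120. Heat shock was kept under 2 of 14 alternatives, and was lost without GW1929 replicate 1 or 2 and without rosiglitazone replicate 2 or 3.

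The Plin2 difference between GW1929 and rosiglitazone was -0.20 ± 0.12 (interval -0.46 to 0.051, adjusted p = 0.377), and that of Fam183b 0.013 ± 0.17 (-0.35 to 0.38). Limma counted 3607 genes at an unadjusted p under 0.05. The 140 calls became 19, 27 and 83 without GW1929 replicates 1, 2 and 3, and 6, 3 and 0 without rosiglitazone replicates 1, 2 and 3. With the covariate for the gradient within groups 35 genes were called, 29 of them among the 140. Median centring gave 81 calls. The count was smaller than that of GW1929 against pioglitazone in the table as deposited, and larger after cyclic loess (123 against 86) and quantile normalization (162 against 105).

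A joint moderated F-test of any difference among the 3 agonists called 276 genes, with 5335 at an unadjusted p under 0.05. The smallest p belonged to Rfc3, a subunit of the clamp loader of DNA replication (adjusted p = 0.00734), with differences from vehicle of -0.42 for GW1929, 0.013 for pioglitazone and 0.14 for rosiglitazone. Ckap2 of the mitotic spindle (-0.46, 0.11 and 0.021), Rrm2 (-0.44, 0.062 and 0.18), Tpx2 (-0.53, 0.16 and -0.089) and Krtap5-3 (0.53, -0.42 and 0.080) followed, each with adjusted p = 0.0114. Plin2 (adjusted p = 0.188), Fam183b (adjusted p = 0.996) and Dgat1 (adjusted p = 0.124) did not pass. The count was 0 without GW1929 replicate 2, 30 and 125 without GW1929 replicates 1 and 3, 1254 and 58 without pioglitazone replicates 2 and 3, and 57 and 67 without rosiglitazone replicates 2 and 3, and 153 without rosiglitazone replicate 1.

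Across genes, the log2 fold changes of the compounds against the same vehicle arrays correlated at r = 0.075 for GW1929 and pioglitazone, 0.33 for GW1929 and rosiglitazone and 0.25 for pioglitazone and rosiglitazone. Unchanged groups simulated against these shared controls gave a mean r of 0.49 (-0.050 to 0.89 over 100 draws). Observed covariances were 0.00154, 0.00544 and 0.00295 against a simulated 0.00569, so the differences were -0.00414, -0.00025 and -0.00274. All 3 observed correlations and covariances lay below these simulated means, so sharing a control group could by itself give values of this size. The draws did not hold the vehicle arrays as controls, so they do not measure what the vehicle arrays contributed. The vehicle group was too small to split. Genes are not independent replicates, and no p was attached to these values. Plin2 was called both for GW1929 and for rosiglitazone, the single gene shared by these lists of 115 and 1.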

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

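The explanations and their predicted values below were written after the counts had been seen and before each test was run.

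A test of the difference itself set GW1929 apart from the other compounds: 1132 genes differed from pioglitazone, 140 from rosiglitazone, and 276 differed among the 3 agonists. Iigp1 (-0.83) and Bub1 (-0.82) were lower with GW1929 than with pioglitazone. A signal also appeared in probe sets that the comparisons did not use, those without a single gene symbol. Of 4013 such probe sets, 122 passed for the mean of the agonists and 518 for GW1929 against vehicle, with 491 higher and 27 lower, while 0 passed for pioglitazone and 0 for rosiglitazone.

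For the 1132 calls between GW1929 and pioglitazone, 3 technical explanations were weighed. Intensity-dependent scaling may account for most of the count, since 86 genes were called after cyclic loess. The median size of the original calls went from 0.39 to 0.30 (median SE 0.094 and 0.089). A gradient shared by arrays within groups may do so as well, since 75 genes were called with it as a covariate. There that size went to 0.31 (SE 0.094 and 0.094), so in both cases most of the fold stayed while most calls ended. The gradient scores also differed between groups, at -16.5, -7.5 and -8.2 with GW1929 and 22.6, -8 and 1.4 with pioglitazone. The covariate can therefore also remove an effect of the compounds along that direction, and the lower count cannot tell these apart. Genomic DNA or repeated sequence on the GW1929 arrays was not excluded, since probe sets annotated to 5 or more symbols lay 0.248 (log2) above those annotated to 2. These classes differed in median intensity (61.2 and 216.4). Their medians were 0.315 and 0.067, against 0.125 and -0.117 for single-symbol genes in the bins at 59.7 and 233.4. Against pioglitazone, the gap between the classes therefore cannot tell this explanation from intensity-dependent scaling. For GW1929 against vehicle the class medians were 0.39 and 0.052, while the same bins stood at 0.043 and -0.038. The gap there was wider than the intensity trend of single-symbol genes. This argues against that trend as its whole cause in the vehicle comparison. All 3 explanations remain open, so the count is not read as biology.

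Regrouping the arrays gave a measure of chance. For the mean of the agonists 2 genes were called, and 3 of 100 splits, the real one included, gave as many, with a highest other count of 322, which points to a structure of the samples. These splits mix the treatments, so that structure can be the treatments themselves. Its 4 lists were matched or passed by 53 of 100 splits (highest other 13). The F-test's 276 genes were reached by 1 of 100, the real one (highest other 99).

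With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Gene counts (real value, splits with as many, highest other) were 115, 1 and 0 for GW1929, 0, 10 and 551 for pioglitazone, and 1, 1 and 0 for rosiglitazone against vehicle. They were 0, 10 and 0 for rosiglitazone against pioglitazone, 1132, 1 and 0 for GW1929 against pioglitazone, and 140, 1 and 0 for GW1929 against rosiglitazone. The split with 551 genes set vehicle replicate 1 and pioglitazone replicates 2 and 3 against the others, which points to a structure of these samples. List counts in the same order were 3, 6 and 7, then 13, 1 and 10, then 1, 8 and 3, then 12, 1 and 6, then 13, 1 and 9, and 7, 1 and 5.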

How the results depend on the processing

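Cyclic loess and the gradient covariate were chosen only after the results were seen. Over all alternatives, named genes that were called kept their call in 429 cases, lost it in 311 and reversed in 0. Called lists kept it in 534, lost it in 221 and reversed in 4. Named genes without a call stayed so in 3039 cases and were called in 20. Genes that were not named are outside these counts, so the shares do not hold for all genes. An intensity trend with a robust prior, and every probe set on its own, moved no count by over 1.5 times. Where a count moved, the cause was not tested, except that a fold threshold can only lower a count. Dim genes limit the rest, since 7524 of 19537 genes had a mean of at least 120.

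Quantile normalization gave 1 gene for the mean, 36 for GW1929 against vehicle, 105 for GW1929 against pioglitazone and 69 by F-test. It gave 7 lists for pioglitazone, 1 for GW1929 against pioglitazone and 3 for GW1929 against rosiglitazone. For GW1929 against vehicle it gave 3 lists, 2 up and 1 down, against 0 up and 3 down in the table as deposited. Median centring gave 31 genes for GW1929, 1 for pioglitazone and 81 for GW1929 against rosiglitazone, and 2 lists for rosiglitazone. A mean intensity of at least 120 gave 7 genes for GW1929, 112 and 212 for GW1929 against pioglitazone and rosiglitazone and 53 by F-test. It gave 5 lists for GW1929, 4 up and 1 down, 6 for rosiglitazone and 4 for rosiglitazone against pioglitazone. It gave 3 each for GW1929 against pioglitazone and rosiglitazone, both with 2 up and 1 down. In the table as deposited these 2 comparisons had 3 up and 10 down, and 2 up and 5 down. Correlations were r = 0.34 for GW1929 with pioglitazone and 0.069 for GW1929 with rosiglitazone. There the median of all genes for GW1929 against pioglitazone was -0.11. There too, 4 lists turned direction relative to other bright genes: proliferation for pioglitazone (0.062) and for rosiglitazone against pioglitazone (-0.057), histone genes for rosiglitazone against pioglitazone (-0.050) and the raised Treg signature for GW1929 against pioglitazone (-0.093). None passed in the turned direction (adjusted p = 0.993, 0.295, 0.994 and 0.927).

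A pseudocount of 16 gave 1 for the mean, 31 for GW1929, 704 for GW1929 against pioglitazone and 123 by F-test. Array weights gave 11 for the mean, 1199 for GW1929, 2 for pioglitazone, 2 for rosiglitazone, 247 for rosiglitazone against pioglitazone, 1151 for GW1929 against rosiglitazone and 1992 by F-test. A fold of at least 1.5 left 30 for GW1929, 69 and 43 for GW1929 against pioglitazone and rosiglitazone and 69 by F-test. Only the 6 arrays compared gave 177, 89 and 377 for GW1929 against vehicle, pioglitazone and rosiglitazone. The replicate block gave 1 for the mean, 14 for GW1929, 295 and 25 for GW1929 against pioglitazone and rosiglitazone and 39 by F-test. Pairing by number was not established, since 3 of 12 arrays were closest to an array of their own number. Such a count cannot exclude pairing.

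With an estimated correlation camera called 0 lists in all 7 comparisons. Fry called 0 lists for the mean, GW1929, pioglitazone, rosiglitazone and GW1929 against rosiglitazone, 5 for rosiglitazone against pioglitazone and 12 for GW1929 against pioglitazone (smallest adjusted p = 0.00187). Cyclic loess gave 1 gene for the mean, 33 for GW1929, 86 for GW1929 against pioglitazone and 67 by F-test, 8 lists for the mean, 1 for GW1929 against pioglitazone and 4 for GW1929 against rosiglitazone, and r = 0.264 for GW1929 with pioglitazone and 0.36 for pioglitazone with rosiglitazone. The gradient covariate gave 2 genes for pioglitazone, 2 for rosiglitazone against pioglitazone, 75 and 35 for GW1929 against pioglitazone and rosiglitazone and 61 by F-test, 5 lists for GW1929 and r = 0.2 for GW1929 with pioglitazone.

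Leaving out each array gave 1 to 4 genes for the mean, 5 to 180 for GW1929, 0 to 1 for pioglitazone, 1 to 1 for rosiglitazone, 0 to 0 for rosiglitazone against pioglitazone, 47 to 3028 and 0 to 83 for GW1929 against pioglitazone and rosiglitazone, and 0 to 1254 by F-test. Lists ranged from 2 to 10 for the mean, 3 to 4 for GW1929, 8 to 20 for pioglitazone, 0 to 2 for rosiglitazone, 9 to 12 for rosiglitazone against pioglitazone, and 12 to 14 and 6 to 9 for GW1929 against pioglitazone and rosiglitazone. Correlations ranged from -0.106 to 0.318 for GW1929 with pioglitazone, 0.081 to 0.555 for GW1929 with rosiglitazone and 0.16 to 0.389 for pioglitazone with rosiglitazone.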

Other observations

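The classes of small nucleolar RNAs, receptors and probe sets by number of symbols, their scores per array and the separate tests of Plin2 and of Fam183b were chosen only after the results were seen.

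Of 44 small nucleolar RNAs, which guide chemical modification of ribosomal RNA, 7 rose and 0 fell with GW1929 against vehicle (median 0.31, 35 above 0), and the medians were 0.029 with pioglitazone and -0.060 with rosiglitazone, with 0 called in each. The class as a whole was not tested. The GW1929 arrays scored 0.087, 0.32 and 0.29 and the vehicle arrays 0.061, -0.18 and -0.11, so GW1929 replicate 1 lay near vehicle replicate 1 and below pioglitazone replicate 3 at 0.104. The median was 0.32 after cyclic loess and 0.18 with the gradient as a covariate. The 1224 olfactory, vomeronasal and taste receptor genes, silent in most T cells and at a median intensity of 17.9, had a median of 0.18 with GW1929, with 33 called, 0.096 with 6 called after cyclic loess, and 0.19 with 35 called with the gradient as a covariate.

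Among probe sets left out of the comparisons, the difference grew with the number of annotated symbols. Against vehicle, GW1929 gave a median of 0.052 for 656 probe sets with 2 symbols, 0.092 for 367 with 3 or 4, and 0.39 for 356 with 5 or more, of which 187 rose and 0 fell. The medians of the last class were 0.074 with pioglitazone and 0.095 with rosiglitazone. Median intensity fell across these 3 classes, at 216.4, 120.6 and 61.2. Among single-symbol genes the GW1929 median also rose as intensity fell, from -0.038 in the bin at 233.4 to 0.043 in that at 59.7. Scores of the class with 5 or more symbols are given next. Its scores were 0.22, 0.34 and 0.37 on the GW1929 arrays and -0.31, -0.020 and -0.35 on the vehicle arrays.

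All 9 agonist arrays lay above all 3 vehicle arrays for 97 genes, Plin2, Fam183b and Dgat1 among them, and below for 30. Other choices of 3 arrays did the same: 51 of 220, the real one included, gave as many genes above, with a highest other count of 977 and a median of 51.5. These choices hold or mix the treatment groups, so they are not a clean measure of chance. The 97 genes are not read as beyond it.

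Lower proliferation genes with GW1929 were weighed against 3 technical explanations. The median against vehicle was -0.28 after cyclic loess, -0.277 with the gradient as a covariate, and at its weakest -0.21 when 1 array was left out, each beyond the -0.2 set before these tests, so none accounts for the fall on its own. These 3 tests cannot address a technical difference shared by all GW1929 arrays, which would coincide with the compound. Genomic DNA or repeated sequence was not weighed for this list. An effect of the compound on these cells stays open and was not tested. Dose, time and cell number are not given, and the list's call was lost with an estimated correlation (adjusted p = 0.262) and by fry.

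Higher Plin2 and Fam183b with all 3 agonists were weighed as a pair. The smaller difference was 0.908 after cyclic loess, 0.875 with the gradient as a covariate and 0.843 without 1 vehicle array. The test fixed in advance also asked both genes to stay called, and after cyclic loess Fam183b did not: it went from 1.01 ± 0.14 to 1.015 ± 0.148 with adjusted p = 0.0523, so its fold was kept and its larger SE and the adjustment ended the call. The test of the pair was therefore not met under cyclic loess, and as fixed it decides nothing about intensity-dependent scaling. It was met with the gradient as a covariate and without 1 vehicle array, where it asked for the fold alone. This argues against these 2 as the whole cause of the folds. Both folds were also kept after cyclic loess (Plin2 0.903 to 0.908, Fam183b 1.01 to 1.015). In this comparison the median differences of the intensity bins ran only from -0.012 to 0.038. These values argue against intensity-dependent scaling as the whole cause of the 2 folds. Alone, Plin2 had 0.908, 0.875 and 0.843 and Fam183b 1.015, 1.032 and 0.929 under the same 3 alternatives. These single-gene bounds were set after the values were seen and asked for no call, so they are no independent test. The Fam183b call itself was lost without vehicle replicate 1 (0.93, adjusted p = 0.175) or 3 (0.99, adjusted p = 0.178). An effect of the compounds on either gene stays open and was not tested further.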
